A study of Mus musculus with 8 samples.

How the data were processed

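Poly(A)-selected RNA libraries were made with the TruSeq kit from TRIzol-extracted total RNA of 8 organoid samples, per the labels' protocols. The submitters' processing notes name STAR 2.7.3, RSEM 1.2.19, DESeq2 1.22.2, DESeq and the mouse build GRCm38, without saying which step each was used for. The annotation release and the use of strand are not given in the sources used here. Without strand, reads of a gene and an overlapping or antisense partner cannot be told apart, and RSEM shares reads between near-identical copies, so values of paralogs and pseudogenes are uncertain.

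The deposited table of estimated counts gives expected counts per gene, of which 10.3% were not whole. They were rounded to whole numbers before testing. The deposited TPM values, which the authors scaled to the same total in each library, served only for an alternative test on log2(TPM + 1). The deposited FPKM values of the same libraries were not used. Gene symbols came from the files. Coordinates came from GENCODE M21 on GRCm38, in which 55094 of 55573 gene rows had their versioned identifier.

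Samples were grouped by the guide's target and the medium in the labels, which give 4 groups of 2. Depth per library lay between 20887229 and 28477325 estimated counts. Counting error is small for most genes at this depth, and the spread between duplicates, with a common biological coefficient of variation of 15.2%, set the precision. Intervals and floors cover counting error only, since reads carry no molecular identifiers. A count of 0 was treated as at most 3 counts over the group, and intervals on ratios are at the 95% level.

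Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15) and normalised by TMM. edgeR 4.0.16 in R 4.3.3 fitted a quasi-likelihood model to all 8 libraries with 4 group means, so that the groups share 1 estimate of the spread, with 4 residual degrees of freedom. All adjusted p-values are Benjamini-Hochberg values from this test, two-sided, with a threshold of 0.05, unless another tool is named. Standard errors were obtained from the fold change and the F statistic. CPM values use TMM-scaled library sizes. The 5 comparisons are the guide effect in each medium, the cholesterol effect with each guide and their interaction.

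The groups, the tests, 24 gene lists, the rule for named genes and all alternatives but 1 were fixed before the data were examined. The lists cover the mevalonate pathway, the sterol branch, sterol uptake and sensing, LXR targets, fatty acid synthesis, sterol esters and lipid droplets, the unfolded protein response, ATF4, p53, proliferation, interferon, NF-kB, hypoxia, NRF2, MAPK and YAP targets, epithelial and other cell types, and RNA quality. limma 3.58.1 tested each list against the other genes with camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation, with adjustment over the lists of a comparison. The rule for named genes took Soat1 and 8 sterol genes, up to 4 called members of each list and up to 2 uncalled ones, and the 8 largest rises and falls among called genes with an average log2 CPM of at least 2, non-overlapping libraries and an established symbol, and for cell types that should be absent the member with the highest level. Genes named outside it are said to have been chosen after their values were seen.

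The tests were checked on simulated data with the means, library sizes and dispersions of the real libraries and 200 changed genes. The changed genes were drawn only from those above a limit on mean CPM, and the seeded list below from those above a higher limit. The recovered shares therefore do not hold for genes at lower levels. For the guide effect in complete medium, with 13892 genes tested, 61% of 100 genes changed 2-fold and 95% of 100 changed 4-fold were recovered, with 11 false calls. For the cholesterol effect with the Rosa26 guide, with 13895 genes, 69% and 96% were recovered, with 15 false calls. For the interaction, with 13888 genes, 32% and 81% were recovered, with 7 false calls. A seeded list of 15 genes raised 1.5-fold in the interaction, with 13893 genes, had an adjusted p of 5e-18 with camera at the preset correlation and 0.08 with an estimated correlation.

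Alternatives were RLE and upper-quartile normalisation, no filter and a filter of 50 counts in 2 libraries, DESeq2 1.42.0, other quasi-likelihood settings, limma-voom, limma on log2 TPM, the 4 compared libraries alone, and leaving out each library. Added after seeing the data was a fit with 1 surrogate variable from sva 3.50.0 for the axis shared by the duplicates. On simulated data with such an axis and 13954 genes, this fit recovered 80% of 2-fold and 98% of 4-fold interactions with 23 false calls. Without the variable, 17% and 75% were recovered with 0 false calls. The simulated axis was the surrogate variable fitted to these same libraries, so a gain was built in. That gain does not show that the real spread between duplicates runs along 1 such axis.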

Results

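Organoids grown from a liver metastasis of a mouse pancreatic ductal adenocarcinoma were profiled by RNA sequencing. Organoids are epithelial cells grown as small 3-dimensional structures. These carried an oncogenic Kras allele, a mutant Trp53 allele, Pdx1-Cre and Cas9, and received either a guide RNA against the Rosa26 locus as a negative control or a guide against Soat1, the gene of an enzyme that esterifies cholesterol for storage. Both kinds of organoid were kept for 24 hours in complete medium or in the same medium with added cholesterol, which the labels put at 50 mM, a unit that could not be checked from the deposited values. The 4 groups held 2 libraries each, 8 in all. Estimated counts per library summed to between 20887229 and 28477325, and 14199 genes were tested.

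The duplicates are described as technical, so p-values measure only the spread between these samples, which may be technical. They differed well beyond counting noise, with a chi-square per gene between 19.1 and 40.5 where counting error alone gives about 1. The first principal component held 64.6% of the variance and separated the guides. Within groups, the difference between duplicates ran along an axis shared by all 4 groups, with correlations across genes between 0.30 and 0.54. A fit with 1 surrogate variable for this axis, chosen after seeing the data, called more genes in each of the 5 comparisons. The share of counts from mitochondrial genes differed along it, from 1.71% to 2.86% with the Rosa26 guide in complete medium and from 2.48% to 3.08% with the Soat1 guide in cholesterol medium.

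The targeted gene was examined first. Soat1 (GRCm38 chromosome 1, 156424525 to 156474331) was lower with its guide in both media. In complete medium it stood at 164 ± 8.52 CPM (SD, n = 2) with the Rosa26 guide and 75.5 ± 3.11 CPM (SD, n = 2) with the Soat1 guide, a log2 fold change of -1.12 (SE 0.12, adjusted p = 0.0026). In cholesterol medium the means were 167 ± 11.8 and 76.6 ± 11.6 CPM (SD, n = 2 each), again a log2 fold change of -1.12 (SE 0.12, adjusted p = 0.0019). The transcript was reduced and not absent. The effect of a guide on the encoded protein was not measured here.

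**Figure D1:**
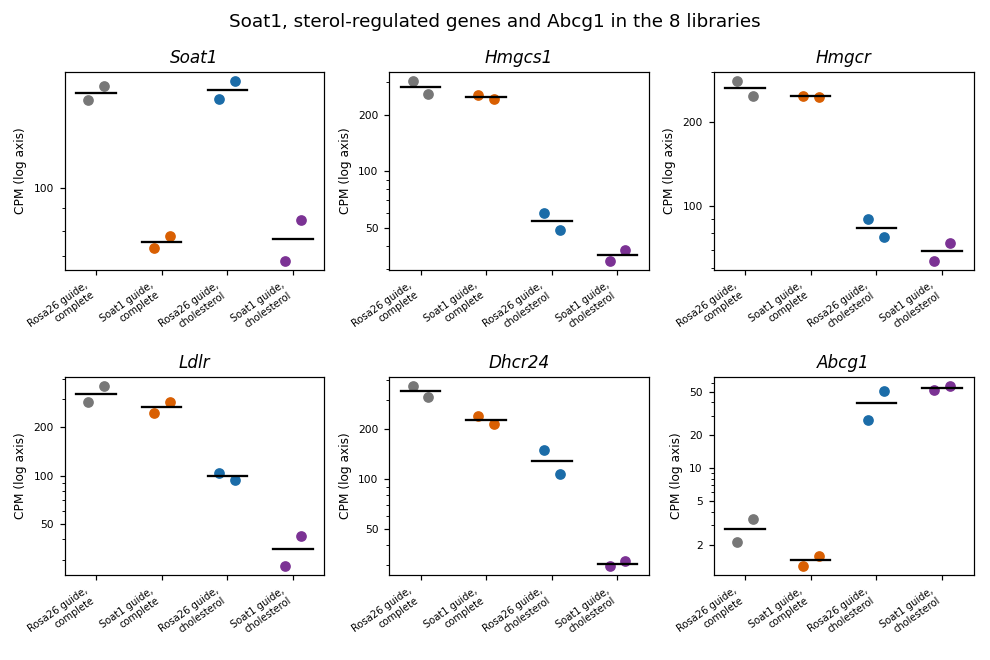
Counts per library scaled to CPM (log axis) of Soat1, 4 sterol-regulated genes and Abcg1 in the 4 groups; each point is a library and each bar the mean of 2. Soat1 was 164 CPM with the Rosa26 guide and 75.5 CPM with the Soat1 guide in complete medium, and Ldlr was 34.8 CPM with the Soat1 guide in cholesterol medium against 98.9 CPM with the Rosa26 guide.

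The first comparison asked how expression differs with the Soat1 guide in complete medium. Called genes with an average log2 CPM of at least 2, non-overlapping libraries and an established symbol were ranked by fitted log2 fold change. The 8 lowest had 0 counts with the Soat1 guide, and for such genes the fitted value depends on the prior count. Eif2s3y and Ddx3y on chromosome Y came below them in this order, with 1911 and 1133 counts against 1 each and ratios of 2040 (95% counting interval 366 to 80700) and 1210 (217 to 47900). Micu2, a regulator of mitochondrial calcium uptake (chromosome 14, 57916261 to 57999262), had 1116 counts over the Rosa26-guide libraries and 0 over the Soat1-guide libraries, at least 398-fold lower against a floor of 3 counts over the group. Fmr1nb was at least 485-fold lower, the Y-linked genes Kdm5d and Uty at least 265-fold and 207-fold, Slco3a1 206-fold, the cilium gene Evc 167-fold, Gspt2 151-fold and the lipoprotein gene Apob 150-fold. Within the same limits, the largest rises were in Fgf13 (log2 fold change 5.71, SE 0.41), the homeobox genes En1 (5.38, SE 0.52) and Hoxb6 (5.16, SE 0.53) and Padi4 (5.18, SE 0.50). The endocytic receptor Lrp2 (4.43, SE 0.42), the kallikrein Klk10 (3.86, SE 0.32), Fbln2 (3.56, SE 0.62) and Trpv4 (3.30, SE 0.42) followed. Adjusted p for these 8 lay between 0.00048 and 0.015.

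Gastric and intestinal epithelial markers formed the group with the clearest change in complete medium. Of 11 tested, 7 fell and 0 rose (9 lower and 1 higher when adjusted over the list alone), with a median log2 fold change of -3.03 and a camera adjusted p of 6.5e-22 (0.01 with an estimated correlation). The secreted trefoil factor Tff1 went from 67.8 ± 3.38 to 0.451 ± 0.214 CPM (SD, n = 2 each; log2 fold change -7.22, SE 0.26, adjusted p = 4.5e-05). Tff3, Anxa10 and the microvillus gene Vil1 fell, with log2 fold changes of -4.88, -5.85 and -3.03. Of 13 ductal and epithelial markers, 5 fell and 1 rose (7 and 2 adjusted over the list alone), with camera adjusted p = 0.023 and adjusted p = 0.34 with an estimated correlation. The keratins Krt8, Krt18 and Krt20 fell, with log2 fold changes of -0.85, -0.81 and -2.24, while Epcam rose by 0.57.

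Of the 9 mevalonate pathway genes and the 13 genes of the sterol branch, edgeR called 0 in complete medium, also when adjusted over the list alone, with 4 at an unadjusted p under 0.05, and 8 and 12 of them had negative fold changes. DESeq2 called 2 of these 22 genes, limma-voom and limma on TPM 0, and the fit with 1 surrogate variable 4, with Sqle, Tm7sf2 and Dhcr24 lower and Ggps1 higher (adjusted p = 0.018, 0.021, 0.0039 and 0.018). Log2 fold changes were -0.17 (SE 0.13) for Hmgcs1, -0.10 (SE 0.12) for Hmgcr, -0.41 (SE 0.23) for Sqle, -0.28 (SE 0.21) for the receptor gene Ldlr, -0.25 (SE 0.16) for Srebf2, -0.05 (SE 0.14) for Srebf1 and 0.74 (SE 0.35) for Insig1. The counting floor allowed no value for the efflux transporter Abca1, with 0 counts in every complete-medium library. In the list of sterol esters and lipid droplets 2 of 9 genes fell (3 lower and 1 higher adjusted over the list alone). The cholesteryl ester hydrolase gene Nceh1 fell by 0.79 (adjusted p = 0.04) and the lysosomal lipase gene Lipa was lower, with 226 counts against 3 and a ratio of 80.5 (95% counting interval 27.2 to 393).

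Single members of other lists moved in complete medium without the list passing its test. Fads1 and Fads2, which desaturate fatty acids, fell, with log2 fold changes of -0.77 and -0.73, and Scd2 rose by 0.95. The cystine transporter Slc7a11 of the ATF4 list rose by 0.99, and Pgd of the NRF2 list fell by 0.99. Of 15 interferon genes 4 rose and 1 fell (6 higher and 2 lower adjusted over the list alone), and Cxcl10, Rsad2 and Oasl2 rose by 2.77, 2.57 and 1.15, from means at or below 1.25 CPM. Of the 2 immune markers tested, Cd68 rose by 1.41 (adjusted p = 0.038), and Itgam had 1 count with the Rosa26 guide against 24 with the Soat1 guide, a ratio of 0.0445 (95% counting interval 0.00108 to 0.273, adjusted p = 0.22). Ccn1 and Ccn2, targets of YAP, fell, with log2 fold changes of -1.28 and -1.57. Pmaip1, Perp, Phlda1 and the glycolytic gene Eno1 fell, with log2 fold changes of -1.13, -0.37, -0.47 and -0.77. Of the NF-kB list, the adhesion gene Icam1 and Birc3 fell, with log2 fold changes of -6.19 and -2.25, and the chemokine gene Cxcl1 was higher (adjusted p = 0.0032), with 2 counts against 102 and a ratio of 0.021 (95% counting interval 0.0025 to 0.0777). Of the 55 genes of the LXR, unfolded protein response, proliferation and RNA quality lists, edgeR, DESeq2, limma-voom and limma on TPM called 0, with 4 at an unadjusted p under 0.05 in edgeR, and the fit with 1 surrogate variable called 11.

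Over all genes, edgeR's quasi-likelihood test called 1263 in complete medium at an adjusted p under 0.05, 488 higher and 775 lower with the Soat1 guide, and 740 of them changed at least 2-fold. The labels name the same parental organoids for both guides and no more than 1 guide-carrying culture each, so an effect of the guide and a difference between those cultures cannot be told apart. Leaving out any library of the comparison moved the count by over 1.5 times, to 578 and 751 without the first and second Rosa26-guide library and to 376 and 374 without the first and second Soat1-guide library.

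The second comparison asked how expression differs with the Soat1 guide in cholesterol medium. The sterol reductase gene Dhcr24 fell from 130 ± 30.1 to 30.8 ± 1.42 CPM (SD, n = 2 each; log2 fold change -2.07, SE 0.17, adjusted p = 0.00061). Ldlr, Idi1, the sterol carrier gene Stard4, Hsd17b7, Sqle, Pcsk9, Srebf2 and Hmgcs1 fell, with log2 fold changes of -1.5, -1.2, -1.15, -0.98, -0.83, -0.75, -0.70 and -0.60, with adjusted p between 0.003 and 0.049. Hmgcr, the rate-limiting enzyme of the pathway, had a log2 fold change of -0.27 (SE 0.12, adjusted p = 0.16), and Ggps1, which leads to isoprenoids, rose by 0.53. In the mevalonate list, 2 of 9 genes fell and 1 rose (2 and 1 adjusted over the list alone; camera adjusted p = 0.16). In the sterol branch 4 of 13 fell (5 adjusted over the list alone), with a median of -0.42 and camera adjusted p = 0.0012 (adjusted p = 0.51 with an estimated correlation). The list of uptake, transport and sensing had 4 of 9 lower and camera adjusted p = 0.064.

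Stress-response genes were higher with the Soat1 guide in cholesterol medium. In the ATF4 list 6 of 12 rose (8 rose and 1 fell adjusted over the list alone; median 0.91, camera adjusted p = 9.8e-06, adjusted p = 0.49 with an estimated correlation), with Trib3, Chac1, Slc7a11 and the transcription factor gene Ddit3 up by 3.42, 2.76, 1.85 and 1.62. In the unfolded protein response list 4 of 12 rose (7 adjusted over the list alone; camera adjusted p = 0.0033, adjusted p = 0.49 with an estimated correlation), among them the chaperone genes Dnajb9 at 1.36 and Hspa5 at 0.52. Of 10 NRF2 targets 5 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.0021, adjusted p = 0.50 with an estimated correlation), with Hmox1 and Srxn1 up by 1.83 and 1.21. Of 15 interferon genes 7 rose (9 adjusted over the list alone; median 1.45, camera adjusted p = 7.1e-08, adjusted p = 0.49 with an estimated correlation). Cxcl10 went from 0.482 ± 0.171 to 13.6 ± 0.241 CPM (SD, n = 2 each), and Rsad2, Ifit1 and Oasl2 rose by 4.88, 4.10 and 3.52. The immune marker Cd68 rose by 1.76 (adjusted p = 0.01), from 3.15 ± 0.717 to 10.7 ± 2.41 CPM (SD, n = 2 each), and Itgam had 3 counts against 44, a ratio of 0.0854 (95% counting interval 0.017 to 0.266, adjusted p = 0.13). The 2 Soat1-guide libraries differed widely in Itgam, at 0.85 ± 1.06 CPM (SD, n = 2), a spread that the counting interval leaves out.

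Proliferation genes were lower with the Soat1 guide in cholesterol medium, with 6 of 22 called (11 adjusted over the list alone), a median of -0.31, and camera adjusted p = 0.0012 (adjusted p = 0.49 with an estimated correlation). Cdk1, Mcm3, Rrm2 and Mcm4 fell, with log2 fold changes of -0.55, -0.51, -0.43 and -0.42. Gastric and intestinal markers were again lower, with 8 of 11 called (8 lower and 1 higher adjusted over the list alone), a median of -2.51 and camera adjusted p = 2.8e-16 (adjusted p = 0.019 with an estimated correlation). The droplet coat gene Plin3, Vegfa, Ndrg1, the phosphatase gene Dusp4 and the p53 target Cdkn1a rose by 1.63, 1.69, 1.76, 1.60 and 0.78. Krt16 rose by 3.77, while Ankrd1, Ccn2 and Ccn1 fell, with log2 fold changes of -2.28, -1.98 and -1.73. Eif2s3y and Ddx3y on chromosome Y, Fmr1nb, Micu2, Gata5, Kdm5d, Gas6 and Uty were at 0 counts and at least 860-fold, 626-fold, 585-fold, 546-fold, 499-fold, 303-fold, 282-fold and 258-fold lower. The LXR, hypoxia, fatty acid, p53, MAPK, YAP, ductal, NF-kB and RNA quality lists did not pass camera's test.

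In all, 2367 genes were called between guides in cholesterol medium by edgeR, 1196 higher and 1171 lower, with 1095 changed at least 2-fold, and limma on TPM called 1243 higher and 758 lower. Without the first or second Rosa26-guide library of this medium 1006 and 1566 were called, and without the first or second Soat1-guide library 1031 and 765.

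The third comparison measured the response of control organoids to added cholesterol. Cholesterol synthesis genes fell. Hmgcs1, which makes HMG-CoA (chromosome 13, 119690379 to 119708260), went from 280 ± 31.9 to 54.3 ± 7.91 CPM (SD, n = 2 each), a log2 fold change of -2.37 (SE 0.14, adjusted p = 0.0057). Msmo1, Idi1, Cyp51, Mvd, Lss, Ldlr, Hmgcr and Pcsk9 fell, with log2 fold changes of -2.41, -2.15, -2.10, -2.09, -2.05, -1.71, -1.65 and -1.43. Sqle, Insig1 and Srebf2 had log2 fold changes of -1.77 (SE 0.23, adjusted p = 0.061), -2.21 (SE 0.37, adjusted p = 0.16) and -1.17 (SE 0.16, adjusted p = 0.074). With 1 surrogate variable these genes passed (adjusted p = 5e-05, 0.0025 and 0.0017). The cholesterol efflux transporter Abcg1 rose from 2.78 ± 0.93 to 39.2 ± 16.3 CPM (SD, n = 2 each; log2 fold change 3.82, SE 0.35, adjusted p = 0.017). Abca1 went from 0 to 34 counts over the group, at least 11.3-fold higher, with adjusted p = 0.21 (0.03 with 1 surrogate variable). Soat1 and Srebf1 had log2 fold changes of 0.03 (SE 0.12) and 0.04 (SE 0.14).

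In the mevalonate list 4 of 9 genes fell (8 adjusted over the list alone), in the sterol branch 6 of 13 (12), in uptake, transport and sensing 2 of 9 (6) and in fatty acid synthesis 3 of 12 (7), the last with log2 fold changes of -1.39, -1.34 and -1.29 for Fads1, Elovl6 and Fads2. With camera and an estimated correlation these 4 lists had adjusted p = 0.011, 0.014, 0.011 and 0.014, LXR targets 0.014 and gastric and intestinal markers, with a positive median of 0.60, 0.028. Of these 11 markers edgeR, limma-voom and limma on TPM called 0, with 2 at an unadjusted p under 0.05 in edgeR, DESeq2 called 1, and the fit with 1 surrogate variable had 6 higher, among them Tff1 and Anxa10 (adjusted p = 0.00052 and 0.013). Another 7 lists passed only at the preset correlation: ATF4 (adjusted p = 0.45 with an estimated correlation), interferon (0.45), p53 (0.20), proliferation (0.48), NF-kB (0.35), YAP and Rho (0.17) and ductal markers (0.17). Of their 97 genes edgeR, limma-voom and limma on TPM called 0, with 15 at an unadjusted p under 0.05 in edgeR, DESeq2 called 4 and the fit with 1 surrogate variable 10, among them Krt8, Rhob and Atf3 (adjusted p = 0.00052, 0.0068 and 0.015).

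In control organoids edgeR called 23 genes, 2 higher and 21 lower, with the keratin gene Krt14 (log2 fold change 1.80) beside Abcg1 among the higher. At an unadjusted p under 0.05 there were 662. The count was 22 and 17 without the second complete-medium library and without the first cholesterol-medium library of this guide, and 5 or 6 without any other of the 8. edgeR on the 4 compared libraries alone called 0, with 441 at an unadjusted p under 0.05, while on all libraries limma-voom called 23 (2 higher) and limma on TPM 29 (1 higher). The balance of directions depended on the method, with 103 called by DESeq2 (45 higher), 124 by edgeR without a filter on low counts (57 higher) and 338 with 1 surrogate variable (200 higher).

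**Figure D2:**
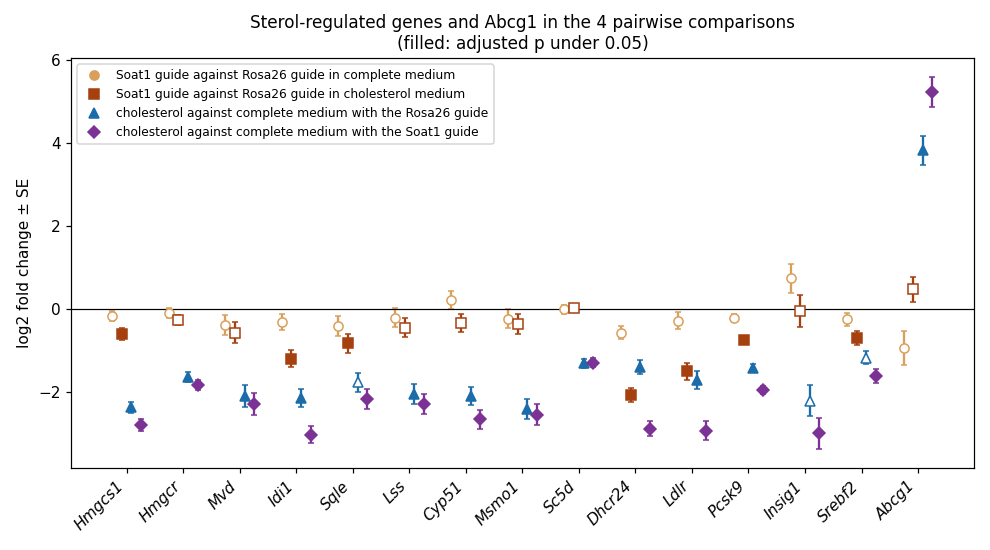
Log2 fold changes with their standard errors (vertical bars) of 14 sterol-regulated genes and Abcg1 in the 4 pairwise comparisons of 2 against 2 libraries; filled symbols have an adjusted p under 0.05. Both cholesterol responses lie below 0 for Hmgcs1, at -2.37 and -2.8, and the guide effect on Dhcr24 is -0.57 in complete and -2.07 in cholesterol medium.

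The fourth comparison measured the response to added cholesterol with the Soat1 guide, and cholesterol synthesis genes fell here too. Idi1, Ldlr, Dhcr24, Fdps, Hmgcs1, Cyp51, Msmo1 and Insig1 fell, with log2 fold changes of -3.03, -2.93, -2.89, -2.82, -2.8, -2.66, -2.55 and -3.0, and Sqle, Hmgcr and Srebf2 with -2.18, -1.83 and -1.62, with adjusted p between 0.00097 and 0.01. In the sterol branch 12 of 13 genes fell, in the mevalonate list 7 of 9 and in uptake, transport and sensing 5 of 9 (12, 8 and 6 adjusted over the list alone, with 1 mevalonate and 1 uptake gene then also higher). These lists and LXR targets held with an estimated correlation (adjusted p = 0.043 for the first 3 and 0.048 for LXR). Abcg1 rose from 1.44 ± 0.218 to 54.1 ± 2.91 CPM (SD, n = 2 each; log2 fold change 5.23, SE 0.37, adjusted p = 0.0018), and Abca1 went from 0 to 31 counts, at least 8.8-fold higher (adjusted p = 0.042). Scd1, Fads2, Fads1 and Elovl6 fell, with log2 fold changes of -2.38, -1.73, -1.61 and -0.99, in a fatty acid list with 5 of 12 lower (6 adjusted over the list alone) and adjusted p = 0.052 with an estimated correlation.

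In the ATF4 list 8 of 12 genes rose with cholesterol in Soat1-guide organoids (9 adjusted over the list alone; median 1.0, camera adjusted p = 6.7e-17, adjusted p = 0.052 with an estimated correlation). Trib3 went from 10.9 ± 5.06 to 96.3 ± 8.13 CPM (SD, n = 2 each; log2 fold change 3.14, SE 0.41, adjusted p = 0.012), and Atf3, Ddit3 and Sesn2 rose by 2.63, 1.96 and 1.06. Of 15 interferon genes 6 rose (9 adjusted over the list alone; median 1.5, camera adjusted p = 4.2e-15, adjusted p = 0.052 with an estimated correlation), among them Cxcl10, Rsad2, Ifit1 and Oasl2 by 4.05, 3.92, 3.60 and 2.15. The immune markers Cd68 and Itgam were not called, with log2 fold changes of 0.89 (SE 0.30, adjusted p = 0.17) and 0.70 (SE 1.03, adjusted p = 0.80). Chaperone genes Hspa5 and Dnajb9 rose by 0.65 and 1.35, with 2 of 12 unfolded protein response genes called (7 adjusted over the list alone; adjusted p = 0.15 with an estimated correlation). The p53 targets Cdkn1a, Pmaip1 and Trp53inp1 rose by 1.48, 2.17 and 2.31 (adjusted p = 0.052 for the list with an estimated correlation), and 1 of 22 proliferation genes, Mcm4, fell by 0.42 (12 adjusted over the list alone; adjusted p = 0.081 with an estimated correlation). Of these 22 genes limma-voom called 1, limma on TPM 3, DESeq2 7 and the fit with 1 surrogate variable 22, all of the last lower. Krt16, Ndrg1, Aldh1a3, Rhob, Areg, Rhoc, Vegfa, Dusp4, Plin3 and Hmox1 rose by 3.66, 3.1, 2.86, 2.11, 1.78, 1.55, 1.36, 1.28, 1.26 and 1.23. The hypoxia, NRF2, MAPK, ductal and gastric lists passed camera's test at the preset correlation, with adjusted p = 0.08, 0.35, 0.19, 0.08 and 0.08 with an estimated correlation.

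**Figure D3:**
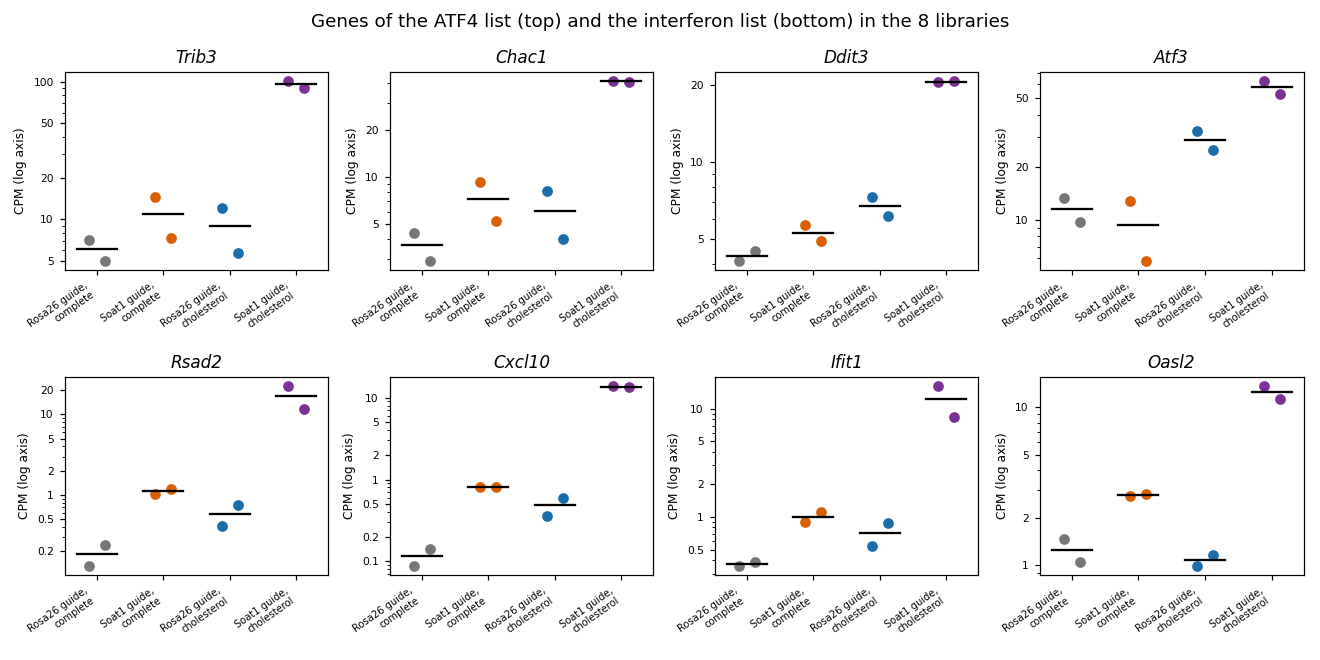
Counts per library scaled to CPM (log axis) of 4 genes of the ATF4 list and 4 of the interferon list in the 4 groups; each point is a library and each bar the mean of 2. Both Soat1-guide libraries in cholesterol medium lie above the other 6 for every gene shown, with means of 96.3 CPM for Trib3 and 13.6 CPM for Cxcl10.

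The test called 498 genes in this comparison, 376 higher and 122 lower, with 229 changed at least 2-fold, and the fit with 1 surrogate variable called 2073 higher and 1591 lower. Without the first or second complete-medium library 106 and 46 were called, and without the first or second cholesterol-medium library 91 and 68.

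The interaction asked whether the cholesterol response differs between the guides. No single gene passed, with 0 called by edgeR and a smallest adjusted p of 0.18, 701 at an unadjusted p under 0.05, 46 called by DESeq2, 0 by limma-voom and 2 by limma on TPM. The fit with 1 surrogate variable, chosen after seeing the data, called 241 genes, 206 higher and 35 lower, among them Vegfa, Dhcr24, Ndrg1 and Trib3 (adjusted p = 0.0056, 0.0059, 0.011 and 0.013). Without that variable, the smallest adjusted p among genes of the 11 lists that passed camera's test belonged to Vegfa (1.57, SE 0.18, adjusted p = 0.25), Ndrg1 (1.92, SE 0.28, adjusted p = 0.27), Oasl2 (2.37, SE 0.34, adjusted p = 0.27), Dhcr24 (-1.5, SE 0.23, adjusted p = 0.27) and Ddit3 (1.32, SE 0.22, adjusted p = 0.33), as log2 differences of the cholesterol effect, Soat1 minus Rosa26 guide. Trib3 and Ldlr stood at 2.58 (SE 0.58, adjusted p = 0.56) and -1.23 (SE 0.29, adjusted p = 0.58). All 12 ATF4 genes and all 12 unfolded protein response genes had positive differences and all 22 proliferation genes negative ones. In the ATF4 list 7 passed when adjusted over the list alone and 3 in the interferon list. At the preset correlation 11 lists passed camera's test, led by ATF4 (median 0.83, adjusted p = 1.2e-16). With an estimated correlation 0 passed, and ATF4, interferon and proliferation each had adjusted p = 0.18.

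The guide effects in the media, which share no library, correlated across genes with Pearson's r = 0.864 and Spearman's rho = 0.71, where genes are not independent replicates. They shared 418 higher and 638 lower calls, against 41.1 and 63.9 for independent lists, with 1 gene called in opposite directions. The cholesterol effects with both guides correlated with r = 0.338 (rho = 0.447) and shared 20 lower and 2 higher calls, against 0.18 and 0.053. The guide effect in complete medium and the cholesterol effect in control organoids share their control libraries. Their r was 0.0386, against 0.496 (0.442 to 0.527) in 20 simulations of unchanged groups. The simulations hold no guide effect, which by its size lowers r in the real data, so the real and simulated r do not compare. Their covariance was 0.021 against a simulated 0.0644. The simulations draw the spread between duplicates as independent noise, without the axis shared by the groups. The real and simulated covariance therefore do not compare either. On differences of log2 CPM, a measure other than the fitted fold changes, the covariance was 0.00952 with both control libraries shared. With 1 control library for each comparison it was -0.0988 and -0.0265. The controls are too few to leave 2 on each side. They also lie at opposite ends of the duplicate axis, at -1.1 and 0.94 of the surrogate variable, which can lower the last 2 values. The 2 effects shared 0 higher and 3 lower calls, against 0.0687 and 1.15 for independent lists, and part of such an overlap may come from the shared controls.

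Positions of the transcripts missing with the Soat1 guide were examined after their values were seen. With at most 12 counts over the 4 Soat1-guide libraries and a mean above 2 CPM over the 4 Rosa26-guide libraries, 105 genes on 20 chromosomes qualified, against 4 in the other direction. Of 6 Y-linked genes tested, Eif2s3y, Ddx3y, Kdm5d and Uty had 3969, 2633, 1468 and 1197 counts over the Rosa26-guide libraries and 1, 1, 0 and 0 over the Soat1-guide libraries. The predicted gene Gm29650 had 61 and 0 counts, while the pseudogene Mid1-ps1 was not missing, with 246 and 310. Medians of some chromosomes were also shifted between the guides. The median log2 fold change of genes on chromosome 15 was -0.227 in complete and -0.232 in cholesterol medium, on chromosome 18 -0.209 and -0.189, on chromosome 19 -0.217 and -0.14, on chromosome 10 -0.168 and -0.156 and on chromosome 17 0.179 and 0.162. On chromosome 18, 82% of 256 genes were lower in complete medium, on chromosome 15 79.3% of 411 and on chromosome 19 62.5% of 392. Whether a shift ran over the whole of a chromosome was not tested.

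**Figure D4:**
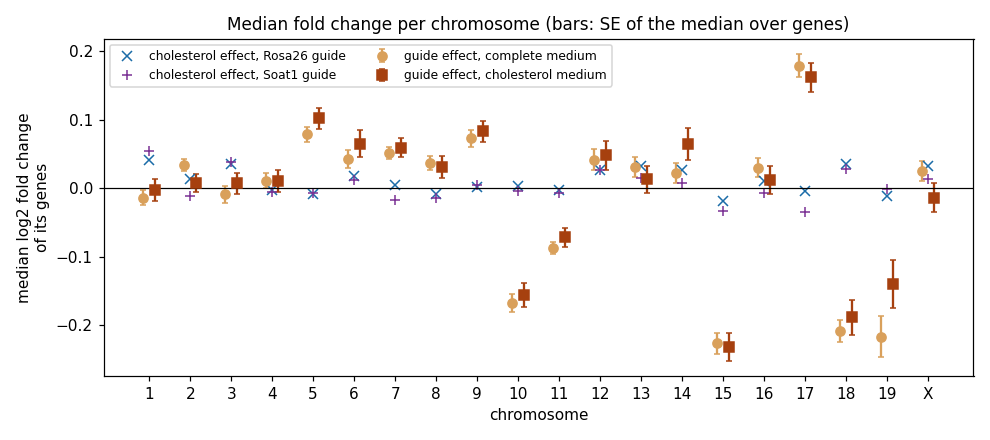
Median log2 fold change of the genes on each chromosome (average log2 CPM of at least 2) for the guide effect in each medium, with the standard error of the median over genes, and for the cholesterol effect with each guide. Chromosomes 10, 15, 18 and 19 lie below 0 and chromosome 17 above 0 for the guide effect in both media, at -0.227 and 0.179 for chromosomes 15 and 17 in complete medium.

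No acinar or fibroblast marker passed the count filter, with highest levels of 0.464 CPM for Cpa2 and 0.442 CPM for Pdgfra in any library. Of the hepatocyte, immune and endothelial markers 2 each were tested, with highest levels of 0.813 CPM for Apoa2, 12.4 CPM for Cd68 and 1.07 CPM for Vwf. Cd68, a lysosomal membrane gene used as a macrophage marker, had 95 and 138 counts with the Rosa26 guide in complete and cholesterol medium and 269 and 579 with the Soat1 guide. Vwf was higher in cholesterol medium, with 3 counts with the Rosa26 guide against 50 with the Soat1 guide, a ratio of 0.0752 (95% counting interval 0.015 to 0.233). The list of histone and mitochondrial transcripts, read as a sign of RNA quality, had 0 of 13 genes called by edgeR, DESeq2 and limma-voom in each of the 5 comparisons, with 1 at an unadjusted p under 0.05 in edgeR (cholesterol with the Soat1 guide) and 1 called by limma on TPM (the guide in cholesterol medium). The fit with 1 surrogate variable called 2 and 4 of them for the guide in complete and cholesterol medium, 2 and 5 for cholesterol with the Rosa26 and Soat1 guides and 0 for the interaction.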

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

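The tests with mitochondrial transcripts, with libraries on either side of the shared duplicate axis and of the spread between duplicates were chosen only after related results were seen.

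Of the lists, 11 responded differently to cholesterol with the Soat1 guide than with the Rosa26 guide by camera's interaction test at its preset correlation, and 0 with an estimated correlation. As median log2 differences of the cholesterol effect, Soat1 minus Rosa26 guide, they were interferon response at 1.05, ATF4 and integrated stress response at 0.83, NF-kB and cytokines at 0.54, unfolded protein response at 0.32, NRF2 targets at 0.16, p53 targets at 0.12, hypoxia and glycolysis at 0.08, the sterol branch at -0.17, the mevalonate pathway at -0.19, proliferation at -0.24 and sterol uptake, transport and sensing at -0.45. The medians of the sterol branch, NRF2 targets and hypoxia and glycolysis changed sign when 1 library was left out, ranging from -0.538 to 0.098 (without the second Rosa26-guide library in complete medium), from -0.036 (without the first) to 0.469 and from -0.025 (without the first Soat1-guide library in cholesterol medium) to 0.124. With 1 library per group from each side of the axis shared by the duplicates, their signs agreed on both sides, at -0.28 and -0.32, 0.13 and 0.20, and 0.09 and 0.07.

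The ATF4 and interferon lists had positive median interactions of 0.83 and 1.05, with camera adjusted p = 1.2e-16 and 1.5e-09 at the preset correlation and adjusted p = 0.18 each with an estimated correlation, and of their 12 and 15 genes edgeR and limma-voom called 0, DESeq2 2 and 1, limma on TPM 0 and 1 and a fit with 1 surrogate variable, chosen after seeing the data, 5 and 2, with 7 in each list at an unadjusted p under 0.05 in edgeR. With all libraries thinned to the smallest total, 20887198 counts, the ATF4 median was still 0.828 and the interferon median 1.058. With 1 library per group from each side of the duplicate axis, the ATF4 median was 0.661 on the lower side and 0.941 on the other, and the interferon median 1.479 and 0.511. The 9 mitochondrial transcripts had a median interaction of -0.0367. This argues only against a culture stress that would move them by 0.4 or more, and a stress that leaves them unmoved stays open. A biological difference between the guides in the handling of added cholesterol may account for the pattern as a hypothesis, and any other difference between the cultures that carry the guides stays open too.

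Of the 22 cholesterol synthesis genes, 6 fell and 1 rose with the Soat1 guide in cholesterol medium and 0 were called in complete medium by edgeR, and 19 had a lower fold change in cholesterol medium. For the guide in cholesterol medium DESeq2 called 8, limma-voom 6, limma on TPM 4 and the surrogate-variable fit 17, of which 16 were lower and 1 higher. In complete medium DESeq2 called 2 and the surrogate-variable fit 4, and for the difference between the media edgeR, limma-voom and limma on TPM called 0, with 4 at an unadjusted p under 0.05 in edgeR, while DESeq2 called 1 and the surrogate-variable fit also 1, Dhcr24 at -1.52 (adjusted p = 0.0059). The median difference between duplicates was 0.283 in complete and 0.217 in cholesterol medium, a ratio of 1.31 that decides nothing, since the model pools 1 spread over all groups and gave median standard errors of 0.224 and 0.23. Thinning to equal totals left 1.01 times the median guide effect in cholesterol medium, -0.443 against -0.438. On the sides of the duplicate axis the median guide effect was -0.33 and -0.06 in complete and -0.63 and -0.24 in cholesterol medium, and the median interaction was -0.31 and -0.24, so a real difference between the media stays open as a hypothesis.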

How the results depend on the processing

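No paired analysis was run because the labels give no replicate numbers. The first-listed library had the lower surrogate variable in all 4 groups, so the shared axis follows the listed order, and a block by that order was not tested. The surrogate-variable fit was chosen after seeing the data. RLE and upper-quartile scaling, limma-voom, the stricter filter and the other quasi-likelihood settings kept all 5 counts of called genes within 1.5 times. Without a filter on low counts, 124 genes were called for cholesterol with the Rosa26 guide (57 higher), 947 with the Soat1 guide and 53 for the interaction. DESeq2 called 103 (45 higher), 928 and 46, and limma on log2 TPM 2 for the interaction. On TPM, which shifted the median of all genes by 0.102 in cholesterol medium, the guide effect there had 1243 genes higher and 758 lower, against 1196 and 1171. With only the 4 compared libraries, 1562 genes were called for the guide in cholesterol medium and 0 for cholesterol with the Rosa26 guide. With 1 surrogate variable the counts were 4057 and 6303 for the guide in complete and cholesterol medium, 338 (200 higher) and 3664 for cholesterol with the Rosa26 and Soat1 guides and 241 for the interaction, and all genes called without it (1263, 2367, 23 and 498) remained. In null simulations with such an axis this fit made at most 8 false calls. With 200 changed genes added, it made 15 for cholesterol with the Rosa26 guide and 23 for the interaction. Without the variable there were 1 and 0. The null simulations therefore do not bound the false calls among the counts above. The cause of the other changes was not tested.

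Leaving out 1 library, which leaves a group with a lone sample assumed to vary like the others, gave 374 to 1182 genes for the guide in complete medium, 765 to 2168 in cholesterol medium, 5 to 22 and 46 to 432 for cholesterol with the Rosa26 and Soat1 guides and 0 to 1 for the interaction, the single gene without the second Rosa26-guide library in complete medium. Fewer libraries remain in these fits. With an estimated correlation, camera passed 1, 1, 6, 4 and 0 lists in place of 2, 7, 13, 15 and 11. The stricter filter moved the correlation of the cholesterol effects from 0.338 to 0.516 and that of the guide and cholesterol effects from 0.0386 to -0.058. Some list medians changed sign when a library was left out, and their lowest and highest values follow. For cholesterol with the Rosa26 guide, ATF4 ranged from -0.051 (without the first cholesterol-medium library of that guide) to 0.402, p53 targets from -0.065 and interferon from -0.01 (both without its second complete-medium library) to 0.297 and 0.695, and proliferation from -0.136 to 0.004 (without its second cholesterol-medium library). For cholesterol with the Soat1 guide, hypoxia ranged from -0.02 (without its second complete-medium library) to 0.14 and MAPK output from -0.01 (without its first cholesterol-medium library) to 0.147. For the interaction, the sterol branch ranged from -0.538 to 0.098 (without the second Rosa26-guide library in complete medium), hypoxia from -0.025 (without the first Soat1-guide library in cholesterol medium) to 0.124 and NRF2 targets from -0.036 (without the first Rosa26-guide library in complete medium) to 0.469. Of the values of named genes under all alternatives, 5926 kept their side of the threshold, 439 lost a call, 348 gained one and 0 called values changed sign. The spread between duplicates, more than depth, limits these comparisons, except for genes at a few counts.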

Other observations

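All tests in this part were chosen after the values were seen, and so were the genes it names. Some transcription factor genes were near absent or lower with the Soat1 guide. Gata6, Gata5, Hnf1a, Foxa3 and Sox4 had 1178, 2199, 655, 422 and 3618 counts over the 4 Rosa26-guide libraries and 2, 4, 2, 3 and 3 over the 4 Soat1-guide libraries. Hnf4a went from 89.3 ± 21.2 to 19.8 ± 8.23 CPM and Foxa2 from 28.4 ± 2.13 to 6.49 ± 0.838 CPM (SD, n = 4 each), with log2 fold changes of -2.53 and -2.15 in complete medium (adjusted p = 0.0013 and 0.00075). Foxa1, Hnf1b and Gata4 had log2 fold changes of 0.21, -0.34 and 0.18 there, with adjusted p of 0.46, 0.13 and 0.32, and of 0.50, -0.15 and 0.69 in cholesterol medium, with adjusted p of 0.053, 0.42 and 0.004. With 1 surrogate variable, Hnf1b passed in complete medium (adjusted p = 0.029) and Foxa1 in cholesterol medium (adjusted p = 0.0068). Homeobox genes moved both ways. Evx1 and Hoxa10 were at 0 counts over the 4 Soat1-guide libraries, at least 166-fold and 68.9-fold lower. In complete medium Hoxb3, Hoxb5 and Hoxb6 rose, with log2 fold changes of 5.18 (SE 0.52), 6.69 (SE 0.78) and 5.16 (SE 0.53). These 3 genes had only 10, 3 and 20 counts over the 4 Rosa26-guide libraries, so the fitted values rest on few counts. En1, the androgen receptor gene Ar, Foxn1 and Notch3 rose in that medium, with log2 fold changes of 5.38, 2.92, 3.12 and 2.75.

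A candidate explanation for the shifted chromosomes is chromosome copy number that differs between the cultures that carry the guides, since chromosome medians of the guide effect correlated between the media, which share no library, with r = 0.974, and 1000 shuffles of genes over chromosomes gave no spread of medians as large (p = 0.001 in each medium, the smallest they can give). The cholesterol effect, which copy number would not give, also had a spread of medians beyond nearly all shuffles (p = 0.001 and 0.002) and r = 0.841 between the guides, so these tests are not specific to copy number, but its spread was smaller, with an SD of 0.0185 and 0.0226 against 0.11 and 0.102 for the guide. The copy number of whole chromosomes is argued against for the 101 missing transcripts outside chromosome Y. No chromosome had a median guide effect below -0.232, while these genes had a median fitted log2 fold change of -7.86 in complete medium. The median over these genes of their chromosome's guide effect was 0.034 in complete and 0.0309 in cholesterol medium. That value decides nothing, since normalisation centres all genes near 0 and these genes are spread over the chromosomes. The median of 50 markers of immune, endothelial, fibroblast, hepatocyte and acinar cells was 0.0338 CPM in the Rosa26-guide libraries. Pooled over 5 lists, this median could not show 1 cell type alone. Such cells there are argued against by the highest mean of any marker, 2.66 CPM for Cd68, against a median of 4.8 CPM for the missing transcripts. Soat1-guide organoids from another animal with 2 X chromosomes and Xist on are argued against by their highest Xist level of 0.129 CPM, although a loss of an X chromosome stays open. For the missing transcripts an effect of the Soat1 guide and any other difference between the cultures stay open, since the labels name no more than 1 culture per guide.

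In the order of the tested genes along the chromosomes, missing transcripts were neighbours in 9 pairs. In 1000 random draws of tested genes the mean was 0.76 and the highest 5. Genes that were not tested may lie between such neighbours. In 2 of these pairs the loci overlap, in 4 (1 of them overlapping) the symbols share their leading letters and 2 lie on the Y chromosome. The other 2 pairs compare with as many or more such pairs in 138 of 1000 draws. Evc, Evc2 and Msx1 follow each other among the tested genes on chromosome 5 (37289098 to 37824583), with 0, 2 and 0 counts over the Soat1-guide libraries. Between the end of Evc2 at 37425055 and the start of Msx1 at 37820485 no gene was tested. Whether short segments were lost was not tested.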
